A study of Mus musculus with 30 samples.

How the data were processed

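The log2 values used here are those deposited by the authors for each probe and array; how they were normalised is not given in the sources used here. They looked quantile-normalised: the largest SD over the arrays of a value at the same rank was 0.00218. Per the labels, RNA was extracted with Trizol, amplified and biotin-labelled with an Illumina TotalPrep-96 kit, and hybridised to mouse whole-genome beadchips. It had been planned, before the data were examined, to background-correct and normalise the non-normalized intensities with neqc. This could not be run, because the 60 columns of that table (30 of signal and 30 of detection) are headed by bare numbers that match no sample label. The groups, comparisons, gene lists, test and most of the alternatives were chosen before the data were examined. The planned filter used the detection p-values, which could not be assigned to samples either. A filter on signal, set from the deposited values and described below, replaced it. Replicates are separate samples by their labels, and the p-values measure the spread between these samples.

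Of 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none. A table of RefSeq genes (GRCm38.p6) served only for names; 34807 probes matched it by gene ID and 0 symbols were updated. The dim level was 7.18, set from the mode of the signal (7.01) and the SD below it (0.07092) so that a share of 0.01 of background probes would lie above it. The 26643 probes above this level in at least 3 arrays were kept, and each gene was represented by its probe with the highest mean, which left 13201 genes. Where no array of a group lay above the dim level, a fold is given as at least the ratio of the other group's mean to that level. Folds are on the deposited scale, without subtraction of background signal, and understate changes of dim genes.

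A linear model with a mean for each of the 9 groups was fitted with limma, with empirical Bayes variances (21 residual and 4.604 prior degrees of freedom, median residual SD 0.1068). Adjusted p-values are from the method of Benjamini and Hochberg, over all genes of a comparison or, where stated, over a list alone, and a gene passed with an adjusted p under 0.05. Effects across times were tested with F-tests. The 38 gene lists, written from general knowledge before the data were examined, were tested with camera, with a preset correlation between genes of 0.01 and with an estimated correlation. Genes named against PBS are, per direction, the 10 with the largest folds among passing genes whose arrays did not overlap between the groups. Where fewer than 3 genes passed, 5 are named by smallest p. Where the agents are compared, 10 are named by smallest p. Up to 4 members of a list are named as well, and Glp1r, Fgf7 and Fgfr2.

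The code was tested on simulated data. For Ex-4 at 20 h, 87.3%, 97.6% and 99.7% of genes changed 1.5-fold, 2-fold and 3-fold were recovered with 2.81% false calls, and at 5 h 92.6%, 98.6% and 100% with 1.64%. Of genes with a smaller simulated change, 47.5% were recovered at 20 h and 62.6% at 5 h. In 20 simulations without any change, a median of 4 to 9 lists passed with the preset correlation, depending on the comparison, and the highest count was 11 to 18. Each count of lists reported below against PBS for the fit of all arrays is under the highest simulated count of its comparison. Without Ex-4 replicate 1, the count at 5 h after Ex-4 was 14, which equals the highest simulated count. An estimated correlation called a list in 0 or 1 of the 20. The median number of genes called was 0 in each comparison, but for Fgf7 at 1 h the mean was 29.35. Lists that passed only with the preset correlation are therefore weak evidence of a change. Versions were R 4.3.3, limma 3.58.1, the package data.table in version 1.17.8, Python 3.11.15 and matplotlib 3.10.9. Alternatives left out 1 array at a time, fitted only the groups compared, added a replicate block, changed the filter and the variance model, or kept all probes; subtraction of background, a smooth muscle covariate and leaving out 4 arrays of high smooth muscle signal were added after the data had been seen. Probes without a symbol were left out of the gene tests, and the non-normalized intensities are not used here.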

Results

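Gene expression was measured in scrapings of the jejunal mucosa, the lining of the middle part of the small intestine, from male mice of the inbred strain C57BL/6. The mice had not been fasted and had been injected once, into the peritoneal cavity, with exendin-4 (Ex-4, 10 nmol/kg), with recombinant human keratinocyte growth factor (Fgf7, 1 mg/kg) or with phosphate-buffered saline (PBS). Ex-4 is an agonist of the receptor for glucagon-like peptide 1, and Fgf7 is a growth factor that acts on epithelial cells through a splice form of the receptor Fgfr2. Tissue was taken 1, 5 or 20 h later, which gave 9 groups with n = 3 at 1 h, n = 4 at 5 h and n = 3 at 20 h. The 30 arrays were Illumina mouse whole-genome beadchips, on which oligonucleotide probes capture labelled cRNA. Array medians were all 7.14 on the log2 scale, and 45.5% to 45.6% of the probes lay above the dim level on each array. Values that look quantile-normalised give such equal figures by construction, so these do not measure the quality of the arrays. Across genes, arrays of the same group correlated with r = 0.988 to 0.996 (median 0.993 over 36 pairs), against a median of 0.991 for the 399 pairs from different groups. Genes are not independent replicates in these correlations.

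The comparisons asked how the mucosal transcriptome responded to each agent against the time-matched PBS group and how the responses differed. Glp1r, the receptor of Ex-4, had a single probe that lay above the dim level in 0 of the 30 arrays, so it was not tested. The endogenous Fgf7 transcript lay above the dim level in 21 of 30 arrays, its highest value was 7.52, and it did not pass in any comparison between groups. Fgfr2 did not pass in any either. Its lowest value against PBS was a log2 difference of -0.42 ± 0.17 (SE, n = 3 per group), 20 h after Fgf7, with an adjusted p of 0.999. The arrays differed in their content of smooth muscle transcripts. The mean centred log2 signal of the 15 smooth muscle genes was 1.65 in PBS 1 h replicate 3, 1.64 in PBS 5 h replicate 3, 0.97 in Fgf7 5 h replicate 2 and 0.71 in Ex-4 5 h replicate 1. It lay between -0.42 and 0.15 in the other arrays.

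**Figure D1:**
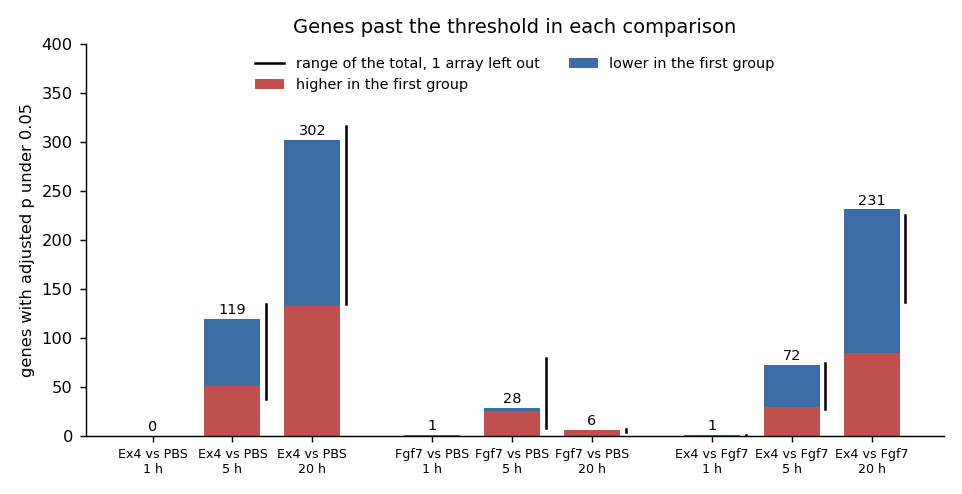
Number of genes with an adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), out of 13201 genes tested, with genes higher in the first group in red and genes lower in it in blue. Black lines give the lowest and highest total when 1 array was left out; Ex-4 against PBS at 20 h had 302 genes and a range of 134 to 316.

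At 1 h after Ex-4, 0 of the 13201 genes passed limma's test against PBS (n = 3 per group), 390 had an unadjusted p under 0.05, and the smallest adjusted p was 1.00. The 5 genes with the smallest p were Esyt3 (at least 1.11-fold lower), Crem, a cAMP-responsive transcription factor (1.21-fold higher), the chemokine Ccl4 (1.53-fold lower), the G protein subunit Gnb5 (1.42-fold higher) and Cryl1 (1.15-fold higher), each with an adjusted p of 1.00. Among the gene lists, the smooth muscle list was lower, with 14 of 15 genes below 0 and a median log2 difference of -0.42 (adjusted p = 1.38e-06 with the preset correlation and adjusted p = 0.496 with an estimated correlation). Without PBS replicate 3, the array with the highest smooth muscle mean, its median was -0.03 and its adjusted p was 0.722. The list of fibroblast and matrix genes was lower as well, with 14 of 16 genes below 0 (adjusted p = 9.81e-05, and adjusted p = 0.496 with an estimated correlation), and its adjusted p was 0.533 without the same array. All 10 genes of the MHC class II list lay below 0, with a median of -0.26 (adjusted p = 0.00365, and adjusted p = 0.507 with an estimated correlation). That list no longer passed without PBS replicate 1 or without Ex-4 replicate 3, with an adjusted p of up to 0.223. The 9 B cell and plasma cell genes had a median of -0.18 (adjusted p = 0.00287, and adjusted p = 0.496 with an estimated correlation) and did not pass without PBS replicate 1 or Ex-4 replicate 3, with an adjusted p of up to 0.171. The median of the B cell and plasma cell list was -0.30 without the 4 arrays of high smooth muscle signal, where its adjusted p was 0.0313 with an estimated correlation, and with the smooth muscle mean as a covariate they were -0.25 and 0.254. In each of these 4 lists, 0 genes passed. In all, 7 of 38 lists passed with the preset correlation, 4 without Ex-4 replicate 3, and 0 with an estimated correlation.

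Among the passing genes whose arrays did not overlap at 5 h after Ex-4, several sterol synthesis enzymes and Asns had some of the largest rises. Nt5e and Ada had the largest falls among them. Asns, asparagine synthetase, rose 2.13-fold (log2 difference 1.09 ± 0.15, SE, n = 4 per group; adjusted p = 0.00041). The sterol pathway enzymes Fdps (farnesyl diphosphate synthase, 2.09-fold), Lss (lanosterol synthase, 1.92-fold), Cyp51 (lanosterol demethylase, 1.87-fold), Sqle (squalene epoxidase, 1.81-fold) and Msmo1 (methylsterol monooxygenase, 1.68-fold) rose with adjusted p-values from 0.000186 for Msmo1 to 0.00474 for Sqle. Also higher were Phlda1, a gene induced downstream of receptor signalling (1.88-fold), Aacs, acetoacetyl-CoA synthetase (1.72-fold), the collagenase gene Mmp13 (1.74-fold) and Gcnt3, a glycosyltransferase of mucin glycans (1.64-fold). Nt5e, which encodes an ecto-enzyme that forms adenosine from AMP, fell 2.34-fold (log2 difference -1.23 ± 0.25), and Ada, adenosine deaminase, fell 2.10-fold (-1.07 ± 0.19). The nucleoside transporter genes Slc28a2b (1.62-fold) and Slc28a2 (1.52-fold), close paralogs whose probes are not certain to tell them apart, were lower too. Other genes that fell were Apol9b (1.88-fold), the linker histone gene H1f2 (1.84-fold), the aspartoacylase gene Aspa (1.83-fold), the growth factor gene Bmp8a (1.62-fold), Adck5 (1.56-fold) and 9130230L23Rik (1.55-fold).

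In total 119 genes passed at 5 h, 51 higher and 68 lower, and 1485 had an unadjusted p under 0.05. Over all genes tested, the arrays of both groups did not overlap in 5.89%, where chance gives 2.86% with 4 against 4 arrays. The count was 70 without PBS replicate 1, 66 without PBS replicate 3 and 37 without Ex-4 replicate 3, and 14 of the 20 genes named above passed in every such fit. The others were Nt5e and Aspa (not passing without PBS replicate 3 or Ex-4 replicate 3, with an adjusted p of up to 0.0694 and 0.0725), Gcnt3 (PBS replicate 1 or Ex-4 replicate 3, up to 0.0925), Mmp13 (Ex-4 replicates 1, 3 and 4, PBS replicates 3 and 4, up to 0.18) and both Slc28a2 genes (PBS replicates 1 to 3, Ex-4 replicates 1, 3 and 4, up to 0.212 and 0.22). Without the 4 arrays of high smooth muscle signal, 30 genes passed, 25 of them among the 119; with the smooth muscle mean as a covariate 126 passed, 110 of them among the 119. When only these groups were fitted 13 passed. The lowest log2 difference among the probes was -0.12 for Lss, 0.02 for Sqle, 0.07 for Mmp13, 0.23 for Asns and 0.03 for Nusap1 (named below), and a second probe of Aspa gave 0.07.

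Of the 18 cholesterol synthesis genes tested, 8 rose, 0 fell and 16 lay above 0, with a median log2 difference of 0.36; adjusted over the list alone, 11 rose. The list passed with the preset correlation (adjusted p = 1.9e-17) and with an estimated correlation (adjusted p = 0.00356). Without the 4 arrays of high smooth muscle signal 3 of its genes passed, and the adjusted p with an estimated correlation was 0.046; with the smooth muscle mean as a covariate 8 passed and it was 0.00559. In the list of lipid absorption and lipoproteins, 3 of 23 genes fell and 0 rose over all genes, and 5 fell and 1 rose when adjusted over the list alone. The 3 were the cholesterol importer gene Npc1l1 (log2 difference -0.48 ± 0.09) and Abcg5 and Abcg8, which together encode a sterol exporter (1.38-fold and 1.52-fold lower). Abcg8 did not pass without PBS replicate 2 or Ex-4 replicate 3, with an adjusted p of up to 0.0725. This list had an adjusted p of 0.00287, and adjusted p = 0.18 with an estimated correlation, and 0 of its genes passed when the 4 arrays of high smooth muscle signal were left out. Of 19 amino acid response genes 3 rose, Asns, Mthfd2 (1.62-fold) and Psat1 (1.49-fold), and 6 when adjusted over the list alone (adjusted p = 1.16e-05, and adjusted p = 0.0594 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, did not pass without Ex-4 replicate 3 (adjusted p = 0.088), and Psat1, an enzyme of serine synthesis, passed in 1 of the 8 fits without 1 array, that without Ex-4 replicate 2. Of the amino acid response genes 1 passed when the 4 arrays of high smooth muscle signal were left out.

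Genes of growth and division lay above 0 as groups at 5 h. In the list of ribosome biogenesis and MYC targets 20 of 21 genes lay above 0, 0 passed over all genes and 4 rose when adjusted over the list alone (adjusted p = 2.51e-08, and adjusted p = 0.176 with an estimated correlation). For DNA replication and S phase 26 of 29 genes lay above 0 and 0 passed (adjusted p = 1.86e-06, and adjusted p = 0.398 with an estimated correlation). For mitosis 19 of 20 lay above 0 and Nusap1, a spindle protein gene, rose 1.49-fold (list adjusted p = 0.000186, and adjusted p = 0.478 with an estimated correlation). Nusap1 passed in 1 of the 8 fits without 1 array, that without PBS replicate 4, and not when the 4 arrays of high smooth muscle signal were left out. Of 12 Paneth cell genes, 10 lay above 0 and 0 passed over all genes (adjusted p = 0.00159, and adjusted p = 0.335 with an estimated correlation). Of 23 genes of the enterocyte brush border, 18 lay below 0, 0 passed over all genes and 4 fell when adjusted over the list alone (adjusted p = 0.000418, and adjusted p = 0.478 with an estimated correlation). In all, 13 of 38 lists passed with the preset correlation and 1, cholesterol synthesis, with an estimated correlation.

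**Figure D2:**
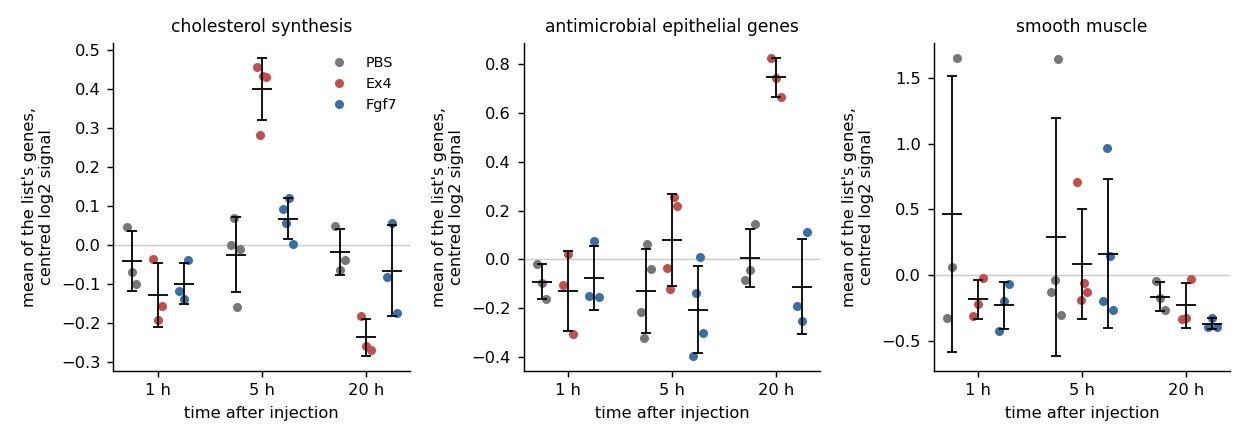
Mean centred log2 signal of the genes of 3 lists (vertical axes) in each array (points) by time after injection (horizontal axes), with PBS in grey, Ex-4 in red and Fgf7 in blue; bars give the mean ± SD of a group (n = 3 at 1 h and 20 h, n = 4 at 5 h). The 4 arrays 5 h after Ex-4 lie between 0.28 and 0.46 for cholesterol synthesis, above all other arrays, and single arrays at 1 h and 5 h stand apart for smooth muscle.

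At 20 h after Ex-4, Saa1, Lcn2 and Gsdmc2 had the largest rises among passing genes whose arrays did not overlap. Dbp, Gsta3 and Cyp2c55 had the largest falls among them. Saa1, an acute-phase serum amyloid gene, rose at least 7.41-fold (adjusted p = 5.08e-13), from a mean of 7.05 in PBS, under the dim level, to 10.07 (n = 3 per group). Lcn2, which encodes a protein that binds bacterial siderophores, rose at least 4.38-fold (adjusted p = 6.68e-09). Also higher were Gsdmc2, of the gasdermin family (4.66-fold), Cyba, a subunit of NADPH oxidases (3.54-fold, log2 difference 1.82 ± 0.17), the glutathione peroxidase gene Gpx2 (3.15-fold), Pglyrp1, a peptidoglycan-binding protein (3.12-fold), Duoxa2, the maturation factor of an epithelial oxidase (3.03-fold), Ltf, lactoferrin (2.40-fold, 1.26 ± 0.12), Capn13 (2.39-fold) and AA467197 (2.34-fold). Dbp, a transcription factor of the circadian output, fell 4.35-fold (log2 difference -2.12 ± 0.24; adjusted p = 3.68e-06). Also lower were the glutathione transferases Gsta3 (3.84-fold), Gstm1 (2.81-fold) and Gsta2 (2.54-fold), the cytochromes P450 Cyp2c55 (3.79-fold), Cyp3a11 (2.58-fold) and Cyp3a25 (2.56-fold), the epoxide hydrolase Ephx1 (3.27-fold) and the aldo-keto reductase Akr1c19 (2.73-fold). Slc5a4b, a member of the sodium and glucose transporter family, fell 2.99-fold.

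In total 302 genes passed at 20 h, 132 higher and 170 lower, and 1612 had an unadjusted p under 0.05. Over all genes tested, the groups did not overlap in 15.05%, where chance gives 10% with 3 against 3 arrays. This share was 9.98% for Ex-4 against PBS at 1 h, where 0 genes passed. It was 14.9% for Fgf7 against PBS at 1 h, where 1 gene passed, so the share alone does not show a broad response. The count was 134 without Ex-4 replicate 1, 167 without PBS replicate 2 and 185 without PBS replicate 3, and all 20 genes named above passed in every fit without 1 array. Without the 4 arrays of high smooth muscle signal, none of which was taken at 20 h, 269 genes passed, 256 of them among the 302. When only these groups were fitted 71 passed. A second probe gave a log2 difference of 0.43 for Saa1, 0.04 for Pglyrp1, 0.05 for Capn13, -0.24 for Gsta3 and -0.10 for Gstm1, and another probe of Per2 gave -0.03. The Gsta and Cyp3a genes have close paralogs, and which member each probe measured is uncertain.

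Of the 15 antimicrobial epithelial genes tested at 20 h, 4 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone (median log2 difference 0.35; adjusted p = 4.55e-06, and adjusted p = 0.0237 with an estimated correlation). Besides Saa1, Lcn2 and Duoxa2, the oxidase gene Duox2 rose at least 1.60-fold. Reg3a, a C-type lectin gene chosen here after its value was seen, fell (log2 difference -0.47 ± 0.10, adjusted p = 0.00672). Without the 4 arrays of high smooth muscle signal, none of them from 20 h, 5 of the 15 genes passed and the median was unchanged at 0.35, while the adjusted p with an estimated correlation was 0.0619; with the smooth muscle mean as a covariate it was 0.0318. Of 13 circadian clock genes, 2 rose and 3 fell, and 2 rose and 6 fell when adjusted over the list alone. Arntl, the partner of Clock in the core loop, rose 1.75-fold (0.81 ± 0.13), and besides Dbp its relative Tef fell 1.87-fold (-0.91 ± 0.18) and the repressor gene Per2 fell 1.99-fold (-0.99 ± 0.18). The clock list had a median of -0.30 and an adjusted p of 0.00019 (adjusted p = 0.356 with an estimated correlation). Of 18 cholesterol synthesis genes 16 lay below 0 and Msmo1 fell 1.74-fold (list adjusted p = 0.00019, and adjusted p = 0.356 with an estimated correlation). Of 21 genes of PPAR alpha targets and fatty acid oxidation 3 fell, among them the retinol saturase gene Retsat (1.96-fold) and the thiolase gene Acaa1b (1.70-fold). That list (adjusted p = 0.0126, and adjusted p = 0.453 with an estimated correlation) did not pass without Ex-4 replicate 1 or PBS replicate 2, with an adjusted p of up to 0.158. All 20 mitosis genes lay above 0 and 0 passed (adjusted p = 0.000374, and adjusted p = 0.659 with an estimated correlation), and the list did not pass without Ex-4 replicate 3 (adjusted p = 0.257). In all, 11 of 38 lists passed with the preset correlation, 7 without Ex-4 replicate 1 or without PBS replicate 2, and 1 of 38, the antimicrobial genes, with an estimated correlation.

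**Figure D3:**
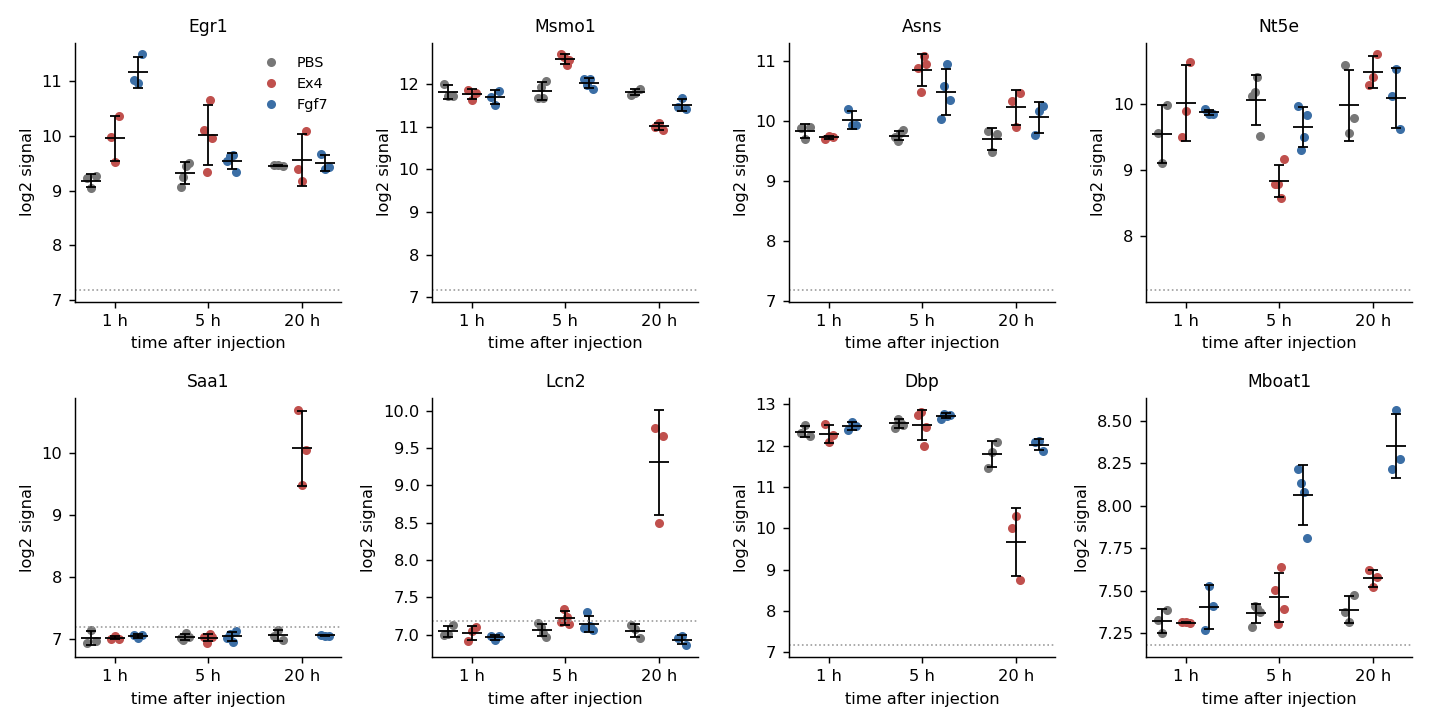
Log2 signal (vertical axes) of 8 genes in each array (points) by time after injection (horizontal axes), with PBS in grey, Ex-4 in red and Fgf7 in blue; bars give the mean ± SD of a group (n = 3 at 1 h and 20 h, n = 4 at 5 h) and the dotted line marks the dim level of 7.18. Saa1 and Lcn2 lie near the dim level in all groups except 20 h after Ex-4, where their means are 10.07 and 9.31.

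At 1 h after Fgf7, Egr1, an immediate-early transcription factor gene induced by growth factor signalling, rose 3.96-fold (log2 difference 1.99 ± 0.24, SE, n = 3 per group; adjusted p = 0.000103). It was the 1 gene that passed, in the fit of all arrays and in each fit without 1 array, and 1000 genes had an unadjusted p under 0.05. The next smallest p-values belonged to Tmem63b (1.27-fold higher), Tmem219 (1.39-fold higher), Pcgf6 (1.24-fold lower) and Siglecg (at least 1.04-fold lower), which did not pass (adjusted p = 0.408 for each). Of the 24 immediate-early genes tested, 1 rose, and the list's adjusted p was 0.0496 (adjusted p = 0.58 with an estimated correlation). That list did not pass without PBS replicate 1 or 2 or without Fgf7 replicate 1 or 3, with an adjusted p of up to 0.213. All 9 B cell and plasma cell genes lay below 0, with a median of -0.33 (adjusted p = 0.000315, and adjusted p = 0.401 with an estimated correlation). The median of that B cell and plasma cell list was -0.43 without the 4 arrays of high smooth muscle signal, where its adjusted p was 0.029 with an estimated correlation, and with the smooth muscle mean as a covariate they were -0.41 and 0.313. All 16 fibroblast and matrix genes lay below 0, with a median of -0.35 (adjusted p = 1.25e-08, and adjusted p = 0.401 with an estimated correlation), which became -0.18 (adjusted p = 0.00986) without PBS replicate 3. All 15 smooth muscle genes lay below 0 as well, with a median of -0.41 (adjusted p = 3.02e-05, and adjusted p = 0.58 with an estimated correlation). Without PBS replicate 3 the smooth muscle median was -0.03 and its adjusted p 0.597. Of 23 brush border genes 20 lay above 0 (adjusted p = 0.000536, and adjusted p = 0.58 with an estimated correlation). In these 4 lists 0 genes passed. In all, 10 of 38 lists passed with the preset correlation, 5 without Fgf7 replicate 1, and 0 with an estimated correlation.

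At 5 h after Fgf7, Srm, Anxa3, Mthfd2, Asns and Mboat1 had the largest rises and Ccl6 the largest fall. Srm, spermidine synthase, rose 1.77-fold (log2 difference 0.82 ± 0.15, SE, n = 4 per group; adjusted p = 0.0174), Mthfd2 rose 1.65-fold, Fpgs, which retains folates in the cell, 1.53-fold, and Asns 1.65-fold. Ncl, nucleolin, rose 1.51-fold (0.59 ± 0.10), Ung, a uracil-DNA glycosylase, 1.55-fold, and Trmt61a, a tRNA methyltransferase, 1.48-fold. The lysophospholipid acyltransferase gene Mboat1 rose 1.62-fold (0.69 ± 0.08; adjusted p = 9.77e-05), the annexin gene Anxa3 1.68-fold, and Etv4, an ETS transcription factor, at least 1.30-fold. The 3 genes that fell were the chemokine Ccl6 (1.77-fold), the secreted phospholipase Pla2g10 (1.34-fold) and the transcription factor Creb3l4 (1.34-fold). In total 28 genes passed, 25 higher and 3 lower, with 903 at an unadjusted p under 0.05. Over all genes tested, the groups did not overlap in 3.23%, where chance gives 2.86%.

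The count at 5 h was 11, 17, 18 and 9 without PBS replicates 1, 2, 3 and 4, and 8, 9 and 79 without Fgf7 replicates 2, 3 and 4. Of the 13 genes named, Anxa3, Ccl6, Etv4, Mboat1 and Ncl passed in every fit without 1 array; the other 8 did not pass without Fgf7 replicate 2, and their adjusted p reached 0.126 to 0.209 over the fits. Without the 4 arrays of high smooth muscle signal 6 genes passed, all among the 28, and 43 passed with the smooth muscle mean as a covariate. A regrouping of these arrays that set replicates 1 and 2 of both groups against replicates 3 and 4 gave 62 genes, more than the 28 of the treatment; with a block for replicate numbers 39 passed, all 28 among them, and 3 passed when only these groups were fitted. Other probes gave log2 differences of -0.05 for Fpgs, 0.02 for Ung and 0.07 for Asns. All 21 genes of ribosome biogenesis and MYC targets lay above 0, with 3 that rose and 9 when adjusted over the list alone (median 0.23; adjusted p = 1.63e-16, and adjusted p = 0.0823 with an estimated correlation). Besides Ncl and Srm the third was Cad, which starts pyrimidine synthesis (1.36-fold; adjusted p of up to 0.258 without 1 array, passing in 1 of the 8 fits, that without Fgf7 replicate 4). Of 29 genes of DNA replication and S phase, 27 lay above 0, and Chaf1b, a chromatin assembly factor, rose (log2 difference 0.49 ± 0.10). Adjusted over the list alone 14 rose (median 0.26; adjusted p = 1.02e-16, and adjusted p = 0.155 with an estimated correlation). Chaf1b did not pass without Fgf7 replicate 2 or 3 or without PBS replicate 3 or 4, with an adjusted p of up to 0.157. Of 19 amino acid response genes Asns and Mthfd2 rose, and 6 when adjusted over the list alone (adjusted p = 0.000859, and adjusted p = 0.155 with an estimated correlation). In each of these 3 lists 0 genes passed when the 4 arrays of high smooth muscle signal were left out. These were the 3 lists of 38 that passed with the preset correlation, and 0 passed with an estimated correlation. The number of lists was 6 without PBS replicate 1, PBS replicate 2 or Fgf7 replicate 2, and 8 without Fgf7 replicate 4.

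At 20 h after Fgf7, 6 genes rose and 0 fell. Anxa3 (2.01-fold, log2 difference 1.01 ± 0.13) and Mboat1 (1.95-fold, 0.96 ± 0.09; adjusted p = 2.35e-06) were higher, as they had been at 5 h. The others were the calcium-binding protein gene S100a6 (1.85-fold), Pate4 (at least 1.34-fold), Etv4 (1.42-fold) and Bcas1 (1.41-fold). Over all genes tested, the groups did not overlap in 9.35%, below the 10% that chance gives, and 530 genes had an unadjusted p under 0.05. Etv4 did not pass without PBS replicate 1 or 2 or Fgf7 replicate 2 (adjusted p of up to 0.226), and Bcas1 without Fgf7 replicate 1 or 2 or PBS replicate 2 or 3 (up to 0.133), and 3 genes passed when only these groups were fitted. All 20 mitosis genes lay above 0, with a median of 0.19 (adjusted p = 2.91e-07, and adjusted p = 0.284 with an estimated correlation). Of 12 Paneth cell genes 10 lay below 0, with a median of -0.41, and 3 fell when adjusted over the list alone (adjusted p = 3.79e-06, and adjusted p = 0.194 with an estimated correlation). All 16 fibroblast and matrix genes lay below 0, with a median of -0.20 (adjusted p = 3.79e-06, and adjusted p = 0.284 with an estimated correlation). So did 13 of 14 blood vessel genes (adjusted p = 0.000125, and adjusted p = 0.289 with an estimated correlation) and 15 of 16 macrophage and dendritic cell genes (adjusted p = 6.38e-05, and adjusted p = 0.289 with an estimated correlation). Over all genes, 0 members of these 5 lists passed. The smooth muscle mean was -0.37 ± 0.04 (SD, n = 3) in these arrays and -0.16 ± 0.11 in PBS. In all, 12 of 38 lists passed with the preset correlation, 7 without PBS replicate 2, and 0 with an estimated correlation.

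Set against each other directly, the agents differed in 1 gene at 1 h, 72 at 5 h and 231 at 20 h. At 1 h Tmem219 was 1.61-fold lower after Ex-4 than after Fgf7 (adjusted p = 0.00639). It did not pass without Ex-4 replicate 2 or 3 or Fgf7 replicate 3 (adjusted p of up to 0.13), and the count was 0 without Ex-4 replicate 2 and without Ex-4 replicate 3. Egr1 was 2.31-fold lower after Ex-4 with an adjusted p of 0.117, so its difference between the agents did not pass. At 5 h, 29 genes were higher after Ex-4 and 43 lower. Among the 10 with the smallest p, Slc52a3, a riboflavin transporter (1.45-fold), Ccl6 (1.80-fold) and Msmo1 (1.47-fold) were higher, and Mboat1 (1.52-fold), Otop3 (1.74-fold), Abhd6 (1.45-fold), Fndc10 (1.41-fold), the phosphatase Dusp16 (1.51-fold), H1f2 (1.64-fold) and Anxa3 (1.61-fold) were lower after Ex-4. Over all genes tested, the groups did not overlap in 5.06% (2.86% by chance), and the count of 72 was 27 without Fgf7 replicate 1, 41 without Fgf7 replicate 4, 33 without Ex-4 replicate 3, 30 without the 4 arrays of high smooth muscle signal, 140 with a block for replicate numbers and 9 when only these groups were fitted. Of the 18 cholesterol synthesis genes 5 were higher after Ex-4, and 12 when adjusted over the list alone (adjusted p = 7.92e-15, and adjusted p = 0.00871 with an estimated correlation). The list of neutrophil and mast cell genes was higher after Ex-4 as well, with 6 genes tested (adjusted p = 0.00664, and adjusted p = 0.043 with an estimated correlation). Its 1 gene that passed, the receptor gene Kit (1.45-fold higher), did not pass without Ex-4 replicate 1, 3 or 4 or Fgf7 replicate 1, 3 or 4, with an adjusted p of up to 0.171.

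At 20 h, 84 genes were higher after Ex-4 than after Fgf7 and 147 lower. Saa1 was at least 7.41-fold and Lcn2 at least 4.38-fold higher, and Ltf (2.37-fold), Capn13 (2.95-fold) and Cyba (2.98-fold) were higher. Dbp was 5.07-fold lower after Ex-4 (log2 difference -2.34 ± 0.24; adjusted p = 1.22e-06), and Cyp3a25 (2.46-fold), Cyp2c65 (1.69-fold) and the glucuronosyltransferases Ugt2b36 (2.18-fold) and Ugt1a10 (1.57-fold) were lower. The 10 genes named at 5 h and the 10 at 20 h passed in every fit without 1 array. Other probes gave log2 differences of -0.00265 for Abhd6 and -0.05 for Dusp16 at 5 h and -0.00504 for Capn13 at 20 h. Over all genes tested, the groups did not overlap in 13.6% (10% by chance), against 13.3% between the agents at 1 h, where 1 gene passed. The count of 231 was 137 without Ex-4 replicate 1 and 139 without Fgf7 replicate 1, and 87 when only these groups were fitted. Of 15 antimicrobial epithelial genes 4 were higher after Ex-4 and 1 lower, and 7 and 1 when adjusted over the list alone (adjusted p = 2.16e-09, and adjusted p = 0.00243 with an estimated correlation).

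The response to Ex-4 differed between the 3 times in 130 genes, by an F-test of the differences from the time-matched PBS groups, and the response to Fgf7 in 3. The strongest for Ex-4 were Saa1 (adjusted p = 2.08e-10), Msmo1 (1.9e-06) and Lcn2 (2.5e-06), and the 3 for Fgf7 were Mboat1, Egr1 and Anxa3. The Ex-4 count was 85 without Ex-4 20 h replicate 1 and 72 without the 4 arrays of high smooth muscle signal. The Fgf7 count was 0 without any 1 of the 3 PBS arrays at 1 h, Fgf7 1 h replicate 1 or 3, or Fgf7 20 h replicate 2, 1 without Fgf7 20 h replicate 3, and 5 without PBS 20 h replicate 2. As a list, cholesterol synthesis after Ex-4 was higher at 5 h than at 1 h (median difference 0.42; adjusted p = 0.00462 with an estimated correlation) and lower at 20 h than at 5 h (median difference -0.53; adjusted p = 0.00258 with an estimated correlation). The antimicrobial genes were higher at 20 h than at 1 h after Ex-4 (median difference 0.35, adjusted p = 0.00896 with an estimated correlation). Between 20 h and 5 h they did not pass (median difference 0.06, adjusted p = 0.171 with an estimated correlation). The glucocorticoid-induced genes were lower at 20 h than at 5 h (median difference -0.37, adjusted p = 0.0493 with an estimated correlation). Between 20 h and 1 h they did not pass (median difference -0.21, adjusted p = 0.163 with an estimated correlation). Against PBS the 19 glucocorticoid-induced genes had an adjusted p of 0.000186 at 5 h after Ex-4 (17 above 0; adjusted p = 0.167 with an estimated correlation), and 0 of them passed. Between the PBS groups themselves, 0 genes passed limma's F-test over the 3 times, 606 had an unadjusted p under 0.05 and the smallest adjusted p was 0.28. That count was 1 without PBS 1 h replicate 1 and 1 without PBS 5 h replicate 4.

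Genes that passed in the same direction for both agents numbered 0 at 1 h, 2 at 5 h and 0 at 20 h. The 2 were Asns and Mthfd2, both higher. Independent lists of these lengths would share 0.112 genes at 5 h. Unchanged groups simulated against the same PBS arrays shared 0 in each of 100 simulations, but such groups give few calls to share, so this 0 decides nothing. The 2 became 0 without any 1 of the 4 PBS arrays or without Fgf7 replicate 2 or 3, 1 without Ex-4 replicate 3 and 5 without Ex-4 replicate 2. With the PBS arrays split between the agents the shared count was 0, but only 11 to 61 genes then passed for Ex-4 and 4 to 14 for Fgf7. Whether the 2 genes were shared through the common PBS arrays is therefore undecided. At 20 h the count was 1 without PBS replicate 1. Across genes the log2 differences of both agents correlated with r = 0.585 at 1 h, 0.481 at 5 h and 0.397 at 20 h, against simulated medians of 0.470, 0.537 and 0.497 with no effect of either agent. The covariances were 0.00868, 0.00652 and 0.00722, against simulated medians of 0.00562, 0.00473 and 0.00508, and each lay within the range of the simulations. With the 4 PBS arrays at 5 h split between the agents, the median correlation over 6 splits was -0.00299 and the median covariance -9.82e-05. Groups of 3 PBS arrays at 1 h and 20 h were too small to be split in this way.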

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

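The splits of arrays were planned; the other 8 tests were chosen only after the data had been seen, the smooth muscle covariate after 4 arrays had stood apart but before its effect on Saa1 and on cholesterol synthesis was computed.

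Smooth muscle genes were lower in both treated groups at 1 h, by a median of -0.42 after Ex-4 and -0.41 after Fgf7, with 0 of 15 genes passing for either agent and adjusted p-values of 0.496 and 0.58 with an estimated correlation. Without PBS replicate 3 the medians were -0.03232 and -0.0279. That array was picked for its high mean over the same genes, so this shows where the difference lay and does not test muscle tissue in 1 control array as its source. An effect of the agents on muscle genes is not excluded either: 1 of the 6 treated arrays lay below both other PBS arrays, but these are few and were left by the same choice. Both explanations stay open.

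Several antimicrobial genes, the acute-phase gene Saa1 among them, were higher at 20 h after Ex-4, while Reg3a was lower. Neutrophils in the scraped tissue would have brought S100a8 and S100a9 along, but the higher upper 95% bound of their log2 changes was 0.1339, while the lower bound of Ltf was 1.019. This argues modestly against neutrophils, since both genes lay near the dim level, from which Saa1 and Lcn2 nevertheless rose. Different muscle content of the scrapings is argued against for Saa1 by the smooth muscle means at 20 h, which overlapped. They were -0.33, -0.33 and -0.03 after Ex-4 and -0.05, -0.18 and -0.27 in PBS. With means so alike the covariate could hardly move Saa1, whose log2 change with it was 3.017. A response of the epithelium itself was not tested and remains possible.

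Cholesterol synthesis genes were higher at 5 h after Ex-4. Different muscle content is argued against, since 8 of the 8 genes that rose still did with the covariate; without the 4 arrays of high smooth muscle signal, and so with fewer samples, 3 genes of the list passed. A fasting-like response was looked for in PPAR alpha targets, whose median log2 change was -0.009248 with 0 genes rising and 1 falling, which argues against a fasting-like rise of these genes. Lower food intake or sterol supply after Ex-4 was not tested and may still contribute.

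Of the clock genes at 20 h after Ex-4, Dbp, Tef and Per2 fell and Arntl and Npas2 rose, while Per1, Per3, Nr1d1, Nr1d2, Ciart and Clock did not pass, and the adjusted p of the clock list was 0.356 with an estimated correlation. The mean log2 differences of the genes that peak with Arntl and of those that peak with Dbp lay 1.121 apart. These sets were drawn up after Dbp and Arntl had been seen to change, so a shift of the clock's phase was not tested and stays open. Collection of the PBS groups at different clock times could not be judged. Between PBS group means Dbp differed by at most 0.7369, with an upper bound of 1.2, and Arntl by 0.385, with 0.629. At 20 h Dbp was lowest (11.8) and Arntl highest (8.375). The unadjusted p of limma's F-test over the PBS groups was 0.0103 for Dbp and 0.00572 for Arntl. Adjusted over all genes these were 0.947 and 0.801. Both genes were picked after they had been seen to change after Ex-4.

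Splits of the arrays into mixed groups asked whether a grouping by chance could give as many calls. For Ex-4 against PBS at 5 h, 1 of 35 splits reached the real count of 119, the real one, and the highest other was 4; for the agents at 5 h it was 1 of 35, with 72 and 1. Only the real split reached these counts, among splits that included those of replicates 1 and 2 against 3 and 4. This argues against chance but does not exclude it. A share of 1 of 35 is the smallest this design can give, and the splits exchanged arrays freely over replicate numbers. For Fgf7 at 5 h, 2 of 35 splits reached 28 and the highest other gave 62, so chance cannot be excluded by the count. That split set replicates 1 and 2 against 3 and 4, which points to a structure of the samples. Over all 12 arrays at 5 h, with treatment in the fit, replicates 1 and 2 differed from 3 and 4 in 118 genes, a contrast chosen because of that split and thus no separate evidence. With a block for replicate numbers, 39 genes passed for Fgf7 and all 28 were kept, and 107 of the 119 were kept for Ex-4 and 70 of the 72 for the agents. Designs with 10 splits are too few for a share under 0.05. Their values (splits reaching the count, the count, the highest other) were 10, 0 and 4 for Ex-4 at 1 h, 1, 302 and 0 at 20 h, 1, 1 and 0 for Fgf7 at 1 h, 1, 6 and 0 at 20 h, 1, 1 and 0 for the agents at 1 h and 1, 231 and 0 at 20 h. Across times, 2 of 100 relabellings reached 130 for Ex-4 with the highest other at 138, a draw that exchanged all Ex-4 and PBS labels at 20 h. For Fgf7, 3 of 100 reached 3 and the highest other gave 6. Few relabellings reached the count for Ex-4, which argues against chance there. The Fgf7 count of 3 was small and ranged from 0 to 5 without 1 array, so chance is not excluded for it. For PBS the real count was 0, which 100 of 100 relabellings reach by construction (highest other 2), as 10 of 10 splits do for Ex-4 at 1 h, so these decide nothing.

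Single arrays were set against their group by Dixon's test, with the critical value for 4 arrays, the group size at 5 h. Groups of 3 arrays, at 1 h and 20 h, are not in the count of 128 tests. The test marks about 1 in 20 by chance (10 of 128 tests here, 6.4 expected), and the arrays that stood apart were as follows. The smooth muscle mean was 1.64 in PBS 5 h replicate 3 and 0.7106 in Ex-4 5 h replicate 1, and the cholesterol synthesis mean was 0.2828 in Ex-4 5 h replicate 2. In PBS at 5 h, Aacs was 9.534 in replicate 2, Fgfr2 10.02 in replicate 3 and Ccl6 9.331 in replicate 4. In Fgf7 at 5 h, Srm was 8.262 and Ccl6 8.244 in replicate 4, and Fndc10 was 9.83 and H1f2 12.06 in replicate 1.

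Responses differed between times in 130 genes for Ex-4 and 3 for Fgf7. Adjusted p-values for Ex-4 were 2.08e-10 for Saa1, 1.9e-06 for Msmo1, 2.5e-06 for Lcn2, 5.16e-05 for Ltf, 8.34e-05 for Cyba and 0.000227 for Gsta3, Cyp3a25, Ephx1, Lss and Akr1c19. Those for Fgf7 were 0.0234 for Mboat1 and Egr1 and 0.0241 for Anxa3. Among 5043 probes without a symbol, 25 passed for Ex-4 at 5 h, 42 for Ex-4 at 20 h and 3 for Fgf7 at 5 h.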

How the results depend on the processing

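Subtraction of background, the smooth muscle covariate and leaving out 4 arrays were chosen only after the results were seen; the other alternatives were planned. Apart from the tests described, the cause of each change was not tested. No named gene that passed reversed. Lists that had not passed could turn, as at 5 h after Fgf7 without the 4 arrays of high smooth muscle signal. There the macrophage and dendritic cell median went from 0.04 to -0.13 (adjusted p = 0.0022, and 0.706 with an estimated correlation). The fibroblast and matrix median went from 0.02 to -0.11 (adjusted p = 0.034, and 0.904 with an estimated correlation).

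Fitting only the groups compared gave 13 genes for Ex-4 at 5 h, 71 at 20 h, 3 for Fgf7 at 5 h, 3 at 20 h, 9 between the agents at 5 h and 87 at 20 h. It gave 1 for the Fgf7 effect across times and 0 shared calls at 5 h. Fewer arrays then estimate the variance, by construction. With a minimum fold change of 1.5, 29 and 115 genes remained for Ex-4 at 5 and 20 h, 9 and 3 for Fgf7, and 21 and 102 between the agents. With variance trend and robust estimation the agents differed in 2 genes at 1 h. With all probes tested, 1 call was shared at 5 h. With background subtracted, 78 genes passed for Ex-4 at 5 h and 2 between the agents at 1 h. With the smooth muscle mean as covariate, 43 passed for Fgf7 at 5 h.

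When leaving out the 4 arrays of high smooth muscle signal, 30 genes passed for Ex-4 at 5 h, 2 for Fgf7 at 1 h, 6 at 5 h and 30 between the agents at 5 h. Then 72 passed for the Ex-4 effect across times, 0 for the Fgf7 effect, 2 for PBS across times, and 0 calls were shared at 5 h. Lists passing were 4 for Ex-4 at 1 h and 6 for Fgf7 at 5 h.

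With all arrays and an estimated correlation, lists passing were 0, 1 and 1 for Ex-4 and 0, 0 and 0 for Fgf7 at 1, 5 and 20 h. After the 4 arrays were left out, B and plasma cell genes passed at 1 h for Ex-4 (adjusted p = 0.0313) and Fgf7 (0.029) with an estimated correlation, and the antimicrobial genes at 20 h after Ex-4 did not (0.0619).

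The pairing of replicate numbers was checked: 22 of 30 same-number pairs correlated above 0.1 (from -0.183 to 0.650; median 0.18, against -0.0652 for other pairs), and 20 of 30 arrays correlated best with an array of their own number. Not all same-number pairs correlated above 0.1, so the samples were not paired in the main fit, which does not show that they are unpaired. Some structure by number is present, which the main fit and the splits of arrays leave out. With a replicate block, 2 genes passed for Fgf7 at 1 h, 4, 140 and 293 between the agents at 1, 5 and 20 h, and 6 for the Fgf7 effect across times.

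Leaving out 1 array gave these ranges of genes: Ex-4 0 to 0, 37 to 134 and 134 to 316 at 1, 5 and 20 h; Fgf7 1 to 1, 8 to 79 and 4 to 7; between the agents 0 to 1, 27 to 74 and 137 to 225. Across times they were 85 to 192 for Ex-4, 0 to 5 for Fgf7 and 0 to 1 for PBS, and shared calls 0 to 0, 0 to 5 and 0 to 1. Lists passing ranged over 4 to 7, 10 to 14 and 7 to 10 for Ex-4, and 5 to 11, 3 to 8 and 7 to 12 for Fgf7.

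Over all alternatives the adjusted p ranged from 0.000131 to 0.0165 for Asns and from 3.98e-05 to 0.0335 for Lss (Ex-4, 5 h), from 2.29e-17 to 0.00333 for Saa1 and from 5.26e-07 to 0.0548 for Dbp (Ex-4, 20 h), from 5.28e-05 to 0.0047 for Egr1 (Fgf7, 1 h), and from 2.48e-07 to 0.0286 for Mboat1 (Fgf7, 20 h). Planned but not run were quantile normalisation without background correction, neqc with an offset of 50 and a block for slides, as columns and slides could not be assigned to samples. Signal over background limits the folds of dim genes.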

Other observations

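The tests of gene families in this part were chosen only after the results were seen.

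At 20 h after Ex-4, some families of drug-metabolising enzymes held more genes that fell than the other genes did. Over 208 families and 1248 tests, 15 of 52 Cyp genes fell (adjusted p = 8.80e-14, Fisher's exact test, median log2 difference over the 52 genes -0.11), with 6 of 13 Ugt genes (adjusted p = 4.15e-06, median log2 difference -0.61) and 5 of 13 Ces genes (adjusted p = 0.000165, median -0.32). Members of such families share regulators and, for some probes, sequence, so these genes are not independent.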
